A study of Homo sapiens with 6 samples.

How the data were processed

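Total RNA from H929 cells, an established human multiple myeloma line, was profiled on 6 Affymetrix whole-transcript arrays. Per the labels, the cells had been nucleofected with a synthetic miR-214 precursor or with a non-targeting control precursor, each at 50 nM, and RNA had been extracted with Trizol and labelled with a whole-transcript sense target kit. There were 3 miR-214 arrays and 3 control arrays. The series text speaks of experiments in triplicate but does not say whether the replicates were separate cultures, so p-values measure the spread between these arrays, which may in part be technical. Groups and replicate numbers were taken from the titles. For miR-214 replicate 3 the title and the transfection label name miR-214 while the free-text description names the control. It was kept in the miR-214 group, and 1 alternative counted it as a control. The values of this array lay with the other miR-214 arrays, so a call lost under that alternative says little against a change.

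The authors' deposited values are intensities on a linear scale with 1 value per transcript cluster for each of 33252 probes. This scale was read from the values themselves, which were all positive and ran from 0.58 to 19469.69. The authors' background correction, summarisation and normalization are not given in the sources used here. No scanner output, detection call, scan date or batch was used. The array medians ran from 166.765 in control replicate 1 to 192.575 in miR-214 replicate 2. The interquartile range on the log2 scale was 2.77 in miR-214 replicate 2 and 2.87 to 2.94 on the other arrays, so the columns had not been brought to 1 identical distribution. The number of arrays limits the precision.

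Probes were named through the platform annotation supplied with the data, with symbols checked by gene identifier against the RefSeq gene table of GRCh38.p14. That table matched 19429 identifiers. Of the 33252 probes, 19460 had 1 gene symbol, 1754 had several and 12038 were unlisted. Only probes with 1 symbol were used for named genes. For 769 genes with more than 1 probe, the probe with the highest mean over all 6 arrays was kept, which left 18417 genes. The files name no genome build, so no coordinates are given, and the gene table served only for names and for which genes neighbour each other. Some of the genes to be named whatever their values are not reported here, and no level is given for MIR214, whose probe is shared with another gene.

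Log2 was taken of the deposited intensities with no pseudocount, no further normalization and no filter on dim genes. Groups were compared with limma 3.58.1 in R 4.3.3 by a linear model with a moderated two-sided test. Benjamini-Hochberg adjustment was over the 18417 genes, and an adjusted p under 0.05 was the threshold. Fold changes are miR-214 minus control. The 26 gene lists with 535 genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and with fry beside it. The fry test asks whether a list's genes move, on balance, one way, and does not compare them with other genes. The lists, the tests and the rule for naming genes were fixed before the data were examined. The licensing and P53 lists were chosen because the series title names DNA replication and P53. Their calls are therefore not independent of the study. Of the listed genes, 10 were on more than 1 list.

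The rule named the 12 highest and 12 lowest fold changes among genes that passed and whose groups did not overlap. It also named a fixed set of genes (PSMD10, ASF1B, CDKN1A, MDM2, MCM5, MCM7, EZH2 and XBP1 among them) and up to 4 members of each list with the smallest p, 113 genes in all. The following genes were named after their values were seen, because few members passed in that direction or because they complete a group: ORC1, ORC2, ORC3, ORC4, ORC5, ORC6, DBF4, RECQL4, ATM, ASF1A, H2BC21, CTNNB1, HDGF, GALNT7, TP53INP1, TIGAR, RRM2B, HERPUD1, HSP90AB1, NFKB1, IFI6, BID, NSD2, MZB1, CCND2, AGO2, SC5D, OR51B2, OR51B4, OR51B5, OR51B6, HBB and HBD.

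The code was tested on simulated data with 18417 genes, 3 arrays against 3 and 200 changed genes, 50 of each size. It recovered 44% of the genes changed by 0.5 on the log2 scale, 94% at 1, 100% at 1.5 and 98% at 2, with 8 unchanged genes among the 176 called. It called 0 lists when none had been moved. The simulated genes varied independently of each other, so this does not test the list calls where genes are correlated. Fewer genes were changed there than the 2256 that passed in the data, and each gene had the same noise on all arrays. The recovered shares therefore need not hold for the data.

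The alternatives were quantile normalization across arrays, a brightness filter on dim genes and the mean over all probes of a gene. Others were an intensity trend with robust variances, array weights, a replicate block and leaving out each array in turn. The last were miR-214 replicate 3 counted as a control, other thresholds and other set tests. The filter left out genes below the 40th percentile of brightness, taken over all 33252 probes and not over the genes. Cyclic loess normalization, a pseudocount of 16, the reported miR-214 targets without PSMD10 and ASF1B, the list counts with each array left out, and a limma test of the per-array differences between list means over all 325 pairs of lists were added after the data had been seen. A planned comparison of genes with and without miR-214 seed sites in their 3' UTRs was not run, because no annotation of 3' UTRs was used here.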

Results

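Gene expression was measured in H929 myeloma cells after nucleofection of a miR-214 precursor or a non-targeting control, both at 50 nM, on 3 arrays per group. The series title names P53 and DNA replication, so the choice of these systems is not independent of the study. The comparison asks how their genes, and the transcriptome around them, differ when miR-214 is supplied. All values are log2 intensities from the deposited table, and differences are miR-214 minus control. In limma, 2256 of 18417 genes passed an adjusted p of 0.05.

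Genes of DNA replication fell in the miR-214 cells. MCM7 and MCM5, subunits of the replicative helicase, fell by 0.95 (SE 0.07) and 0.92 (SE 0.10) on the log2 scale, with limma adjusted p = 0.00171 and 0.00399. MCM7 went from 11.20 ± 0.01 in the controls to 10.25 ± 0.10 with miR-214 (SD, n = 3 each), and MCM5 from 10.45 ± 0.05 to 9.53 ± 0.17. MCM2 was 2.17-fold lower and MCM4 2.11-fold lower. CDT1, which loads the helicase at origins, was 1.93-fold lower, and MCM10 was 1.97-fold lower.

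In the list of replication licensing and initiation, 19 of 25 measured genes fell, 0 rose and 6 did not pass. Adjusted over the list alone, 19 fell as well. The list mean fell by 0.70 on the log2 scale, with array values from -0.77 to -0.64 with miR-214 and an SD of 0.03 among the controls (n = 3). Within the origin recognition complex the subunits parted. ORC1 fell by 1.11 and ORC6 fell by 0.71, whereas ORC2, ORC3, ORC4 and ORC5 did not pass, at -0.12, -0.08, -0.04 and 0.06. The other members that did not pass were DBF4, at 0.18, and RECQL4, at -0.02. By limma's camera the list lay below the other genes at adjusted p = 9.78e-17, and the call was lost at adjusted p = 0.0804 with an estimated correlation.

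Genes of the replication fork followed, with 24 of 33 lower and 0 higher, and 27 lower when adjusted over the list alone. TIMELESS and TIPIN, partners that stabilise stalled forks, fell by 1.02 and 0.96, POLE3 fell by 0.87 and the sliding clamp PCNA fell by 0.76. Of 22 genes of nucleotide synthesis and the G1/S transition, 16 fell and 0 rose, and adjusted over the list alone 19 fell. The phosphatase CDC25A fell by 1.19, the thymidylate synthase TYMS fell by 0.91 and the kinase CDK2 fell by 0.83. The camera adjusted p was 8.99e-20 for the fork list and 1.82e-14 for the G1/S list. With an estimated correlation neither call held, at adjusted p = 0.0804 and 0.0883.

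Mitotic and DNA repair genes were lower as well. Of 31 mitosis genes 22 fell and 0 rose, and all 31 fell when adjusted over the list alone. BIRC5, which encodes survivin, fell by 1.09. A second, dimmer probe of this gene, with a mean log2 of 6.14 against 8.19, was at -0.28 and did not pass. The checkpoint genes MAD2L1 and BUB1B fell by 0.86 and 0.63, and the kinesin KIF2C fell by 0.78. Among 24 genes of homologous recombination and the Fanconi pathway, 17 fell, and 20 when adjusted over the list alone. The exonuclease EXO1 fell by 1.14, FANCI fell by 1.04, and FANCG and RAD54L fell by 0.86 each, while the damage kinase ATM alone rose, by 0.28. The ATM call was lost without any 1 array except miR-214 replicate 2, which left 0 higher repair genes, with 1 at an unadjusted p under 0.05 in limma. The camera adjusted p was 8.36e-19 for mitosis and 5.85e-14 for repair, and with an estimated correlation adjusted p = 0.0804 and 0.142.

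Of 20 histone genes, 10 fell and 1 rose, or 14 and 3 adjusted over the list alone. H2AC8 fell by 1.25, H1-5 fell by 0.75, H3C10 fell by 0.75 and H3C2 fell by 0.71, while H2BC21 rose by 0.30. The H2BC21 call was lost without any 1 array except miR-214 replicate 2, which left 0 higher histone genes, with 3 at an unadjusted p under 0.05 in limma. The camera adjusted p was 5.98e-07, and adjusted p = 0.0804 with an estimated correlation. Histone genes are near-identical copies of each other, so the value of any single one is uncertain. Without miR-214 replicate 2, whose deviations from its group mean had an SD of 0.222 against 0.097 to 0.162 on the other arrays, the counts of lower genes were 19 for licensing, 26 for the fork, 17 for G1/S, 23 for mitosis, 16 for repair and 11 for histones. Without miR-214 replicate 3, whose labels contradict each other, they were 18, 19, 11, 13, 13 and 7. Without 1 of the control replicates they were 14 to 16, 16 to 17, 8 to 9, 8 to 10, 9 and 6 to 7.

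**Figure D1:**
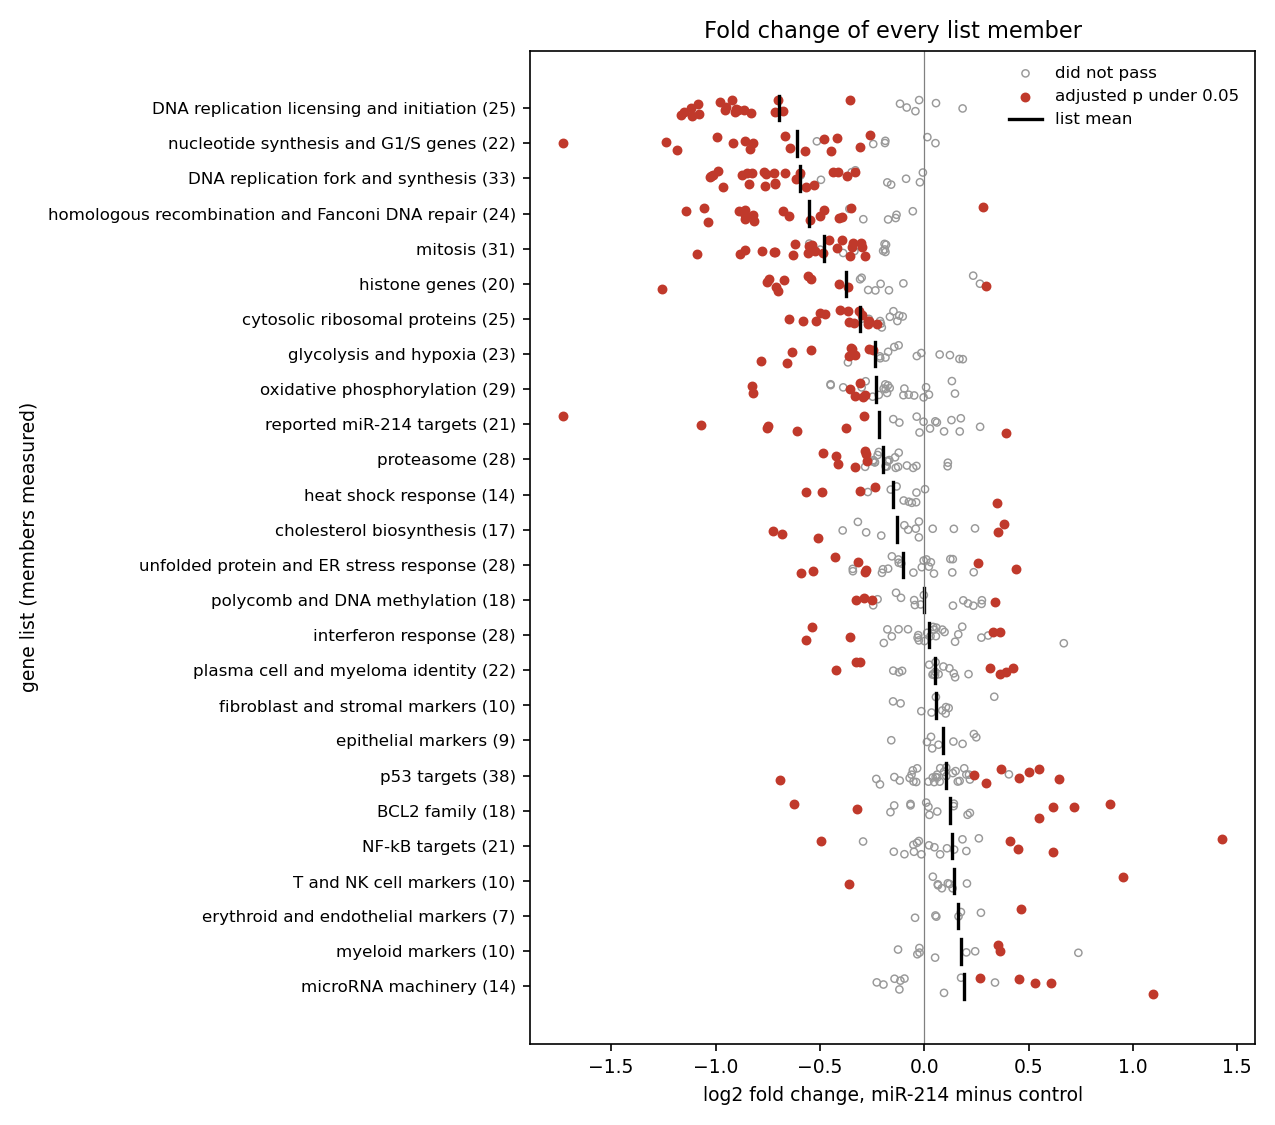
Log2 fold change, miR-214 minus control, of every measured member of the 26 gene lists (points, n = 3 arrays per group), with members past a limma adjusted p of 0.05 filled and the list mean as a bar. The licensing list has the lowest mean, at -0.70, and the microRNA machinery list the highest, at 0.19. The means of the interferon list and the polycomb and DNA methylation list lie near 0. Their shifts against the mean of the other genes, not plotted here, change sign under quantile or cyclic loess normalization.

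Several targets of P53 rose. CDKN1A, which encodes the cell cycle inhibitor p21, was 1.37-fold higher, from 8.54 ± 0.02 to 8.99 ± 0.05 (SD, n = 3), with limma adjusted p = 0.00768. MDM2, the ubiquitin ligase that degrades P53, was 1.18-fold higher, from 12.53 ± 0.03 to 12.77 ± 0.02, with limma adjusted p = 0.046. The receptors EDA2R and TNFRSF10B rose by 0.65 and 0.55, TP53INP1 rose by 0.50, TIGAR rose by 0.37 and RRM2B rose by 0.29. PERP, a desmosomal protein that P53 induces, fell by 0.69.

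These were the 7 genes that rose and the 1 that fell among 38 measured P53 targets, and 30 did not pass. The counts were also 7 and 1 when adjusted over the list alone. The list mean was higher by 0.10, against an SD of 0.02 among the control arrays and 0.03 among the miR-214 arrays (n = 3 each), and 27 of 38 members had a positive fold change. The counts were 7 and 2 without miR-214 replicate 2, and 3 and 1 without miR-214 replicate 3. They were 3 and 1, 1 and 1, and 2 and 1 without control replicates 1, 2 and 3, and 4 and 1 without miR-214 replicate 1. By limma's camera the adjusted p was 0.024, and adjusted p = 0.142 with an estimated correlation. The camera call was also lost without control replicate 3 (adjusted p = 0.0637), without miR-214 replicate 1 (adjusted p = 0.0874) and with miR-214 replicate 3 counted as a control (adjusted p = 0.069). The limma call of CDKN1A was lost without control replicate 2 (adjusted p = 0.0554) and with a replicate block (0.0687). MDM2 lost its limma call without any 1 array except miR-214 replicate 2 (adjusted p = 0.0869 to 0.17) and with the block (0.175). With miR-214 replicate 3 counted as a control both calls were lost (limma adjusted p = 0.514 for CDKN1A and 0.562 for MDM2).

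Genes reported as direct targets of miR-214 went in both directions. PSMD10, which encodes the oncoprotein gankyrin, was 2.10-fold lower, from 11.68 ± 0.04 to 10.60 ± 0.08 (SD, n = 3), with limma adjusted p = 0.0012. The histone chaperone gene ASF1B was 3.32-fold lower, from 10.41 ± 0.04 to 8.68 ± 0.17 (limma adjusted p = 0.0012), while its paralog ASF1A did not pass, at 0.05. RASSF5 and GALNT7 fell by 0.75 each, MAP2K3 fell by 0.61, HDGF fell by 0.38 and the polycomb methyltransferase EZH2 fell by 0.29. CTNNB1, which encodes beta-catenin, rose by 0.39. The plasma cell transcription factor XBP1 did not pass, at -0.15 with limma adjusted p = 0.152, but was lower with an intensity trend and robust variances (adjusted p = 0.00089) and with array weights (0.0318).

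Of 21 measured genes on the list, 7 fell and 1 rose, and 7 and 2 when adjusted over the list alone. The study is known to have named PSMD10 and ASF1B as targets, so these counts are not independent evidence of the direction. The list mean was -0.22 and its median -0.02, with a camera adjusted p of 0.0431 and adjusted p = 0.484 with an estimated correlation. Without PSMD10 and ASF1B the mean of the 19 others was -0.09 and did not pass (camera adjusted p = 0.278, with 5 lower and 1 higher). The counts of the full list were 7 and 1 without miR-214 replicate 2, and 4 and 1 without miR-214 replicate 3. Without any 1 control replicate they were 4 and 0, with 7 and 2 at an unadjusted p under 0.05 in limma. The camera call was also lost under quantile (adjusted p = 0.0665) or cyclic loess normalization (0.0676), with the filter on dim genes (0.1), with array weights (0.0655), without miR-214 replicate 2 (0.181), without miR-214 replicate 3 (0.0627), and with miR-214 replicate 3 counted as a control (0.269). The EZH2 call was lost without any 1 array except miR-214 replicate 2, at limma adjusted p = 0.051 to 0.125.

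**Figure D2:**
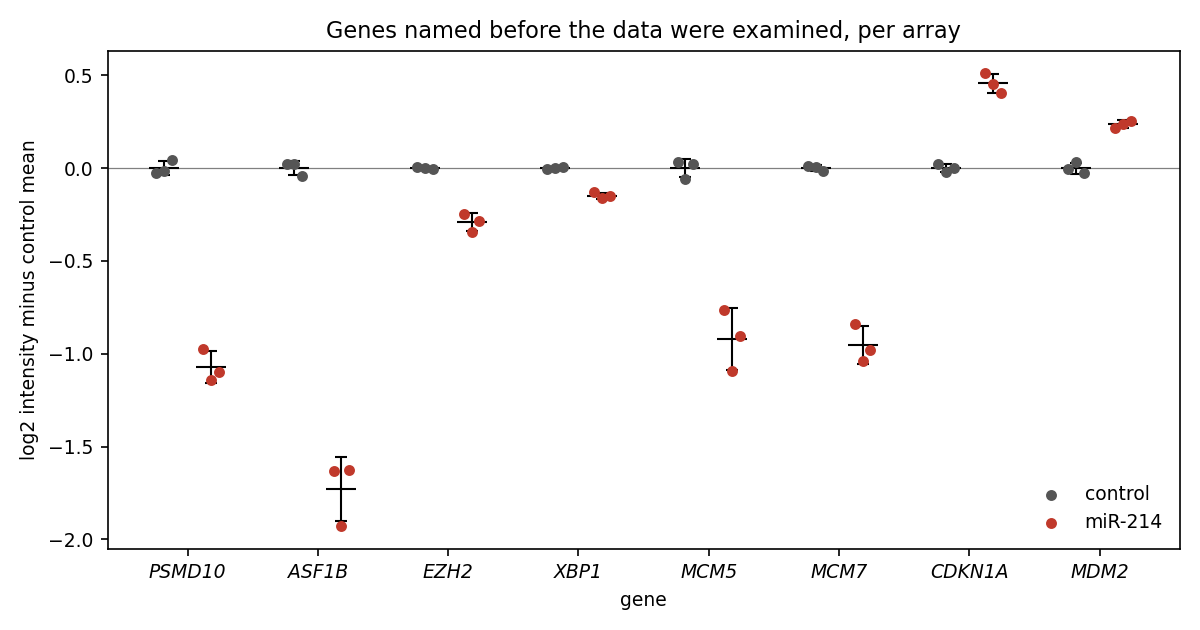
Log2 intensity of genes chosen before the data were examined, each array minus the control mean (points, 3 control and 3 miR-214 arrays; bars, mean and SD). The study is known to have named PSMD10 and ASF1B as targets, and the series title names P53 and DNA replication. The choice of genes is therefore not independent of the study. PSMD10, ASF1B, MCM5 and MCM7 lie lowest with miR-214, with differences of -1.07, -1.73, -0.92 and -0.95, and CDKN1A and MDM2 lie above the controls on all 3 miR-214 arrays.

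Across all genes, 965 were higher and 1291 lower, so 42.8% of the changed genes were higher. At an adjusted p of 0.1 the count was 3352, and 4837 genes had an unadjusted p under 0.05. The groups did not overlap for each of the 2256 genes that passed, and for 33.5% of all genes, where chance gives 10%. At least a 2-fold change was seen for 26 higher and 50 lower genes that passed. Of the 112 named genes that passed, 43 lost the limma call without at least 1 array, and these were all of those with an adjusted p of 0.00768 or more. With miR-214 replicate 3 counted as a control all 112 lost it, but that array lay at 0.956 between the controls (0) and the other miR-214 arrays (1). Without 1 array the count fell to 679 (control replicate 1), 553 (control replicate 2), 697 (control replicate 3) or 869 (miR-214 replicate 3), and the higher genes numbered 570 without miR-214 replicate 1 and 1469 without miR-214 replicate 2. The count was 3419 with an intensity trend and robust variances, 5479 with array weights and 0 with miR-214 replicate 3 counted as a control, where 1696 genes had an unadjusted p under 0.05 in limma.

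The gene with the highest fold change was SMAD3, a transducer of TGF-beta signals, at 3.68-fold higher, from 7.66 ± 0.13 to 9.54 ± 0.11 (SD, n = 3; limma adjusted p = 0.0012). The ubiquitin ligase DTX3L was 3.25-fold higher, the chromatin organiser SATB1 3.20-fold, the tight junction protein TJP1 3.06-fold, HEG1 2.80-fold and CREBRF 2.69-fold. The cell surface molecules CD96, SIRPG and CD1A were 2.54-fold, 2.5-fold and 2.31-fold higher. In the controls DTX3L, SATB1, CD96, SIRPG and CD1A lay at 6.94, 6.28, 6.50, 7.15 and 7.05, below the array medians of 7.38 to 7.59. With miR-214 these genes lay above the medians, but without detection calls the sizes of their fold changes are uncertain. The chemokine CCL3 was 2.69-fold and SPRR2A 2.62-fold higher, and both belong to families with near-identical copies, so their values are uncertain. The small nucleolar RNA SNORA36C was 3.25-fold higher with an SE of 0.27 on the log2 scale, and its limma call was lost without control replicate 2 (adjusted p = 0.0646) or miR-214 replicate 3 (adjusted p = 0.0559).

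Next to ASF1B, the lowest fold changes were those of CGA, the alpha chain of glycoprotein hormones, at 3.06-fold lower, and ENTREP3 and the PCNA-associated factor PCLAF, at 2.70-fold and 2.69-fold. CCDC167 was 2.66-fold lower, and TMEM258, a subunit of the oligosaccharyltransferase, and MAPK3, which encodes the kinase ERK1, were 2.65-fold lower each. SCAMP3, the progranulin gene GRN and the embryonic globin gene HBE1 were 2.46-fold, 2.44-fold and 2.42-fold lower. UHRF1, which recruits DNA methylation to replicated DNA, was 2.36-fold lower (limma adjusted p = 0.012). A second, dimmer probe, with a mean log2 of 6.54 against 9.03, differed by 0.11 and did not pass. The UHRF1 call was lost without any 1 of the controls, at adjusted p = 0.0538 to 0.064. For PCLAF the second probe was also lower, at -0.50.

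Genes of protein synthesis and turnover were lower by smaller amounts. Of 25 cytosolic ribosomal protein genes, 15 fell and 0 rose, and 20 fell when adjusted over the list alone. RPS20 fell by 0.65, RPL27A fell by 0.58, RPS3 fell by 0.48 and RPS2 fell by 0.40. These genes have many processed pseudogenes, so single values are uncertain. By limma's camera the adjusted p was 8.15e-13, and among the 26 lists this call alone also held with an estimated correlation, at adjusted p = 0.0314. Of 28 proteasome genes, 7 fell and 0 rose, or 15 and 0 adjusted over the list alone, with PSMD2 at -0.49, PSMA1 at -0.42, PSMA6 at -0.41 and PSMD3 at -0.27. The proteasome list had a camera adjusted p of 1.46e-07, and adjusted p = 0.142 with an estimated correlation.

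Of 28 genes of the unfolded protein response, 6 fell and 2 rose, or 9 and 2 adjusted over the list alone. SDF2L1 fell by 0.59, the serine synthesis enzyme PHGDH fell by 0.53 and the chaperone DNAJC3 fell by 0.43, while PPP1R15A, which restarts translation after stress, rose by 0.44 and HERPUD1 rose by 0.26. Of 14 heat shock genes, 4 fell and 1 rose, and 4 and 1 also when adjusted over the list alone. HSPE1 fell by 0.57, HSPH1 fell by 0.49, HSPD1 fell by 0.31 and HSP90AB1 fell by 0.24, and the haem oxygenase gene HMOX1 rose by 0.35. The camera adjusted p was 0.0244 for the unfolded protein list and 0.0111 for heat shock, with adjusted p = 0.268 and 0.157 at an estimated correlation. Without miR-214 replicate 3 the unfolded protein list had 1 lower and 0 higher genes and the heat shock list 0 lower and 0 higher genes, with 9 and 2, and 4 and 1, at an unadjusted p under 0.05 in limma. Without any 1 of the controls or miR-214 replicate 1 the counts were 1 to 2 lower and 0 to 1 higher for the unfolded protein list (unadjusted, 8 to 11 and 2 to 4), and 0 to 2 lower and 0 higher for heat shock (4 and 1). Both calls were lost under quantile (adjusted p = 0.191 and 0.0665) and cyclic loess normalization (0.192 and 0.0676), with the filter on dim genes (0.1 and 0.054) and with miR-214 replicate 3 counted as a control (0.069 and 0.0898), and that of the unfolded protein list also with array weights (0.0655), without control replicate 1 (0.0603) and without miR-214 replicate 2 (0.0872).

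Energy metabolism genes were lower as groups. Of 23 genes of glycolysis and hypoxia, 10 fell and 0 rose, and 14 fell when adjusted over the list alone. The mitophagy receptor BNIP3 fell by 0.78, the glycolytic enzymes GPI and ALDOC fell by 0.66 and 0.63, and the glucose transporter SLC2A1 fell by 0.54. Of 29 genes of oxidative phosphorylation, 7 fell and 0 rose, and 15 fell when adjusted over the list alone, with UQCRC1 at -0.82, NDUFV1 at -0.36, NDUFA2 at -0.31 and ATP5F1B at -0.29. The camera adjusted p was 2.03e-06 and 1.46e-06, and with an estimated correlation adjusted p = 0.142 for both. Without miR-214 replicate 3, the count of lower genes was 4 for ribosomal proteins, 1 for the proteasome, 4 for glycolysis and 0 for oxidative phosphorylation, while the camera calls of these 4 lists held. Without any 1 of the controls or miR-214 replicate 1 it was 3 to 8, 0 to 2, 4 to 8 and 0 to 4. In limma, an unadjusted p under 0.05 with a lower value was found for 19 to 20, 11 to 17, 12 to 14 and 12 to 17 genes when any 1 of these 5 arrays was left out.

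Of 22 measured plasma cell genes, 4 rose and 3 fell, or 5 and 3 adjusted over the list alone. The myeloma surface antigens CD38 and SLAMF7 rose by 0.43 and 0.39, the B cell coactivator POU2AF1 rose by 0.36 and the histone methyltransferase NSD2 rose by 0.31. SSR4 fell by 0.42, MZB1 fell by 0.32 and the cyclin CCND2 fell by 0.31. The list did not pass camera, at adjusted p = 0.257, and adjusted p = 0.371 with an estimated correlation, but passed fry (adjusted p = 0.0167). Of the plasma cell genes, 1 was higher and 0 lower without miR-214 replicate 3, and without any 1 of the controls or miR-214 replicate 1, 0 to 2 were higher and 0 to 2 lower. In each of these 5 limma fits 5 were higher and 3 lower at an unadjusted p under 0.05.

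Of 28 interferon response genes, 2 rose and 3 fell, and 3 and 3 when adjusted over the list alone. IRF9 and OAS2 rose by 0.37 and 0.33, and IFI35, BST2 and IFI6 fell by 0.57, 0.54 and 0.35. The interferon counts were 0 higher and 1 lower without miR-214 replicate 3, with 3 and 3 at an unadjusted p under 0.05 in limma. Without any 1 of the controls or miR-214 replicate 1, 0 were higher and 0 to 3 lower, with 3 to 6 and 3 to 4 unadjusted. The list did not pass camera, at adjusted p = 0.823. Its small positive shift against the mean of the other genes turned negative under quantile and cyclic loess normalization.

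Markers of other cell types did not pass camera as lists, while by fry the myeloid list did (adjusted p = 0.0235). Among 10 T and NK cell markers NKG7 rose by 0.95 and GNLY fell by 0.36. Among 10 myeloid markers CD68 and LYZ rose by 0.36 each, and among 7 erythroid and endothelial markers PECAM1 rose by 0.46. LYZ was dim, at 6.06 in the controls. The LYZ call was lost under quantile (limma adjusted p = 0.147) and cyclic loess normalization (0.191), with an intensity trend (0.0941) and with a pseudocount (0.0533). That of PECAM1 was lost with the mean over its probes (limma adjusted p = 0.43), of which the second was dim, at a mean log2 of 4.95. Without any 1 array except miR-214 replicate 2, 0 of the myeloid and 0 of the T and NK cell markers were higher or lower in limma apart from NKG7, with 2 to 3 myeloid markers higher and 1 T and NK cell marker lower at an unadjusted p under 0.05. None of the 10 stromal or 9 epithelial markers passed in limma, where 0 of the stromal and 1 of the epithelial markers had an unadjusted p under 0.05. The camera adjusted p was 0.303, 0.2, 0.123, 0.552 and 0.303 for these lists, and adjusted over each list alone the same numbers of genes passed. Without control replicate 3 the erythroid and endothelial list passed camera, at adjusted p = 0.0449. On all 6 arrays with an estimated correlation its camera adjusted p was 0.484.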

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

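The tests in this part were chosen only after the data had been seen. Probes that the platform annotation lists for several genes were left out of every comparison. Tested by themselves in limma, 125 of these 1754 probes were higher and 127 lower in the miR-214 arrays at an adjusted p under 0.05. Of the 1754, 198 repeat the values of another probe, so these counts include repeats. Among the named genes 12.2% passed, so calls among these probes are not by themselves particular to them. No gene is named from them. Among the 12038 probes that the annotation does not list, limma called 0, with 1278 at an unadjusted p under 0.05. These probes were dimmer, with a mean log2 of 6.92 against 8.09 for the named genes. The absence of calls therefore does not show that none of them changed.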

How the results depend on the processing

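Cyclic loess, the pseudocount of 16, the target list without PSMD10 and ASF1B, and the list counts with each array left out were chosen only after the data had been seen. The other alternatives were set beforehand. Shifts of lists are here the list mean minus the mean of the other genes, on the log2 scale. None of the 2256 changed genes reversed under any setting that tested it. The count of changed genes stayed within 2062 to 3046 under quantile normalization, cyclic loess, the pseudocount, the mean over probes and the brightness filter. It was 3419 (2007 lower) with an intensity trend and robust variances, 5479 (2583 higher, 2896 lower) with array weights, 557 at a 1.5-fold minimum, and 0 (0 higher, 0 lower) with miR-214 replicate 3 counted as a control. Leaving out each array in turn gave 553 to 3000 changed genes, 227 to 1469 higher and 326 to 1531 lower. The count rose, to 3000, without miR-214 replicate 2, whose deviations had the largest SD (0.222), and fell without each of the others. Each of these fits has fewer residual degrees of freedom, so a lost call is not by itself a lost difference. Where both lost their calls, EZH2 was at -0.29 without control replicate 1 and -0.31 without miR-214 replicate 1. MDM2 was at 0.24 and 0.25 in the same fits. How far this accounts for the counts was not tested.

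With a replicate block, 231 genes passed, 92 higher and 139 lower. The deviations of same-numbered arrays from their group means correlated at 0.03, -0.28 and -0.27, which shows no pairing by replicate number. Differences in scaling between arrays enter these deviations, so a pairing is not excluded. The block also uses up residual degrees of freedom.

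The licensing list kept its direction and passed in every setting (-0.74 to -0.65 with each array left out) except with an estimated correlation, where the shift is -0.71 by construction and the adjusted p was 0.0804. The P53 target list was 0.071 to 0.111 with each array left out. It did not pass without miR-214 replicate 1 (0.071, adjusted p = 0.0874), without control replicate 3 (0.078, 0.0637), with miR-214 replicate 3 as a control (0.073, 0.069) or with an estimated correlation (0.092, 0.142), over a range of camera adjusted p from 0.00842 to 0.142. By fry, which sets the list against no change and not against other genes, the adjusted p was 0.00485. Of the other 24 lists, 12 passed camera. With an estimated correlation 1 did, the ribosomal proteins, and by fry 18 did. In these losses the cause was not tested.

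The lists that reversed did not pass in any of those settings. The interferon list, at 0.0098, went to -0.0028 under quantile normalization, -0.028 with the brightness filter and -0.0067 under cyclic loess, and ranged from -0.011 to 0.041 with each array left out, with -0.00073 without control replicate 1. The polycomb and DNA methylation list, at -0.014, went to 0.018, 0.0097 and 0.022 under the same 3 settings. The stromal list went to -0.011 with array weights, and the epithelial list ranged from -0.011, without miR-214 replicate 2, to 0.148. The cause was not tested.

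Of the 113 named genes, 3 changed their side of the threshold under quantile normalization, 3 under cyclic loess, 112 with miR-214 replicate 3 as a control, 60 with the block, and 2 to 41 with an array left out. The comparison of genes with and without miR-214 seed sites was not run. No detection calls or background signals were used, so dim genes have no measured limit of detection here.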

Other observations

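In this part the tests that weigh brightness against the fall of the lists were set before their results were seen. The tests of miR-214 replicate 2, of the labels of miR-214 replicate 3, of cyclic loess normalization, of licensing against mitosis and of other splits of the arrays, and the look at the globin neighbours, were chosen only after the result was seen.

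Genes of the BCL2 family moved both ways. Of 18 measured genes 4 rose and 2 fell, and the same numbers passed when adjusted over the list alone. The pro-apoptotic BMF and BCL2L11, which encodes BIM, rose by 0.89 and 0.55 on the log2 scale (limma adjusted p = 0.0012 and 0.00503), and the anti-apoptotic BCL2 and BCL2A1 rose by 0.72 and 0.62. BCL2L12 fell by 0.62 and the pro-apoptotic BID fell by 0.32. The list did not pass limma's camera, at adjusted p = 0.26, but passed fry (adjusted p = 0.00424). Without any 1 array except miR-214 replicate 2, 3 to 4 were higher and 1 lower. Among 21 NF-kB targets, 4 rose and 1 fell, also adjusted over the list alone. Beside CCL3 and BCL2A1, the inhibitor TNFAIP3 rose by 0.45 and BCL3 rose by 0.41, while NFKB1 fell by 0.49, and the list had a camera adjusted p of 0.204 and a fry adjusted p of 0.00515. In the NF-kB list 1 was higher and 0 lower without miR-214 replicate 3, and without any 1 of the controls or miR-214 replicate 1, 1 to 2 were higher and 0 to 1 lower. At an unadjusted p under 0.05 in limma these 5 fits had 4 higher and 1 to 2 lower. The TNFAIP3 call was lost under quantile (limma adjusted p = 0.0799) and cyclic loess normalization (0.0566).

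Of 14 genes of the microRNA machinery, 5 rose and 0 fell, also adjusted over the list alone. The Argonaute gene AGO4 rose by 1.10, AGO2 rose by 0.27, and the GW182 genes TNRC6B, TNRC6C and TNRC6A rose by 0.61, 0.53 and 0.46. Without miR-214 replicate 3 or any 1 of the controls, 3 were higher and 0 lower, with 5 to 6 and 0 to 1 at an unadjusted p under 0.05 in limma. The list did not pass camera (adjusted p = 0.0866, and 0.291 with an estimated correlation), but did so by fry (0.00215), under quantile (0.0265) or cyclic loess normalization (0.0271), without control replicate 1 (0.0462) and without miR-214 replicate 2 (0.0334). Among 17 genes of cholesterol synthesis, TM7SF2, FDPS and DHCR7 fell by 0.72, 0.68 and 0.51 while SC5D and INSIG1 rose by 0.38 and 0.36, and 6 fell and 3 rose when adjusted over the list alone (camera adjusted p = 0.101, fry 0.0344). Of these genes 3 were lower and 0 higher without miR-214 replicate 3, and without any 1 of the controls 1 to 2 lower and 0 higher, with 6 to 7 and 2 to 3 at an unadjusted p under 0.05 in limma. Of 18 polycomb and DNA methylation genes, the methyltransferase genes DNMT1 and EZH2 and the histone-binding RBBP7 fell by 0.33, 0.29 and 0.25 and TET2 rose by 0.34, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.552). Without any 1 array except miR-214 replicate 2, 0 were lower and 0 to 1 higher, with 4 to 5 and 2 to 3 at an unadjusted p under 0.05 in limma. The RBBP7 call was lost under quantile (limma adjusted p = 0.115) and cyclic loess normalization (0.0746).

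HBE1 and its next 3 protein-coding neighbours on 1 side of it on chromosome 11, in the order of GRCh38.p14, were all lower. HBE1 fell by 1.28, OR51B4 fell by 1.03, OR51B2 fell by 0.99 and OR51B5 fell by 1.10, with limma adjusted p = 0.0012, 0.00585, 0.0155 and 0.0295. The miR-214 arrays spread widely for OR51B4, OR51B2 and OR51B5, with SDs of 0.23, 0.34 and 0.48 (n = 3). Among the controls these SDs were 0.08, 0.10 and 0.06. OR51B5 was dim with miR-214, at a mean log2 of 6.92. The next gene, OR51B6, was at -0.05 and did not pass, and neither did HBD, at 0.03, or HBB, at 0.27, on the other side. The 2 protein-coding genes between HBE1 and HBD are not analysed here. Transcripts of neighbouring genes can overlap here, so the values of single genes are uncertain.

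The real split of the 6 arrays gave 2256 changed genes in limma and was the only 1 of the 10 splits into equal groups to give that many. The highest count among the others was 0, where unadjusted p under 0.05 was found for 169 to 994 genes. With 10 splits a share under 0.05 cannot be reached.

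The fall of the replication licensing genes was set against a brightness-dependent difference in scaling, since miR-214 replicate 2 had a narrower range than the other arrays. None of 10000 random lists matched on brightness had a mean as low as -0.70, the lowest being -0.27, and the share of 1e-04 is the smallest that so many lists can give. The fall did not rest on miR-214 replicate 2, since the mean shift of the other miR-214 arrays was -0.66 and the control arrays spanned 0.05. The 105 genes of the ribosomal protein, oxidative phosphorylation, glycolysis and proteasome lists had a mean of -0.24, again with a share of 1e-04 (lowest random mean -0.12). Without miR-214 replicate 2 their shift was -0.23. These 4 lists were pooled as lists that were lower, which favours a low share, so it is not independent evidence of their fall. Quantile and cyclic loess normalization, which ended the calls of the unfolded protein and heat shock lists, left the licensing list at -0.69 and -0.68 below the other genes and the 4 other lists past the camera threshold, which argues against scaling between arrays as the whole cause. With an estimated correlation, on the deposited values, the camera call held for the ribosomal proteins alone (adjusted p = 0.0314), and it was lost for licensing (0.0804) and for the proteasome, glycolysis and oxidative phosphorylation lists (0.142 each). An effect of miR-214 may be a candidate explanation for both groups of genes, as a hypothesis, beside RNA quality and the authors' background correction, which were not tested and stay open.

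The description of miR-214 replicate 3 names the control transfection. On an axis from the controls (0) to the other miR-214 arrays (1), over the 869 genes called without it, this array lay at 0.956. Each control array left out in the same way lay at 0.010 to 0.039, and the other miR-214 arrays at 0.843 and 0.901. This argues against RNA of control-transfected cells, and the description may be an error in the labels, which alone cannot show which of them is right.

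The licensing genes fell further than the mitosis genes. The mean of the licensing list minus that of the mitosis list was lower on all 3 miR-214 arrays than on all 3 control arrays, with a difference of -0.22 (SD 0.02 in each group, n = 3). By limma over the 325 pairs of list means the adjusted p was 0.0010, and 0.00025 to 0.00811 without each array. The pairs share their lists, so their differences depend on each other, whereas limma treats them as separate. The p-values of this test may therefore be too small, and they do not decide whether the spread between arrays alone is the cause. An exact two-sided permutation test of 3 against 3 arrays gave p = 0.1, the smallest it can give, and cannot decide it either. What the values show is a difference of -0.22 beside an SD of 0.02 in each group. Brightness-dependent scaling as the whole cause is argued against by a difference of -0.23 after either quantile or cyclic loess normalization (limma adjusted p = 0.00052 and 0.000299). A stronger response of licensing genes to miR-214 may be the reason, as a hypothesis, and a difference between the probes of the lists in how far they register a change was not tested.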
